A study of Mus musculus with 2 samples.

How the data were processed

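Histone H3 lysine 9 acetylation (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos (strain B6NCrl) at embryonic day 12.5. Per the labels, 2 biological replicates were made, each from a pool of male and female embryos: 120 embryos for replicate 1 and 88 for replicate 2. Both belong to 1 group, so the series holds no second condition. Comparisons were made between the replicates, between peaks and the gene annotation, and between gene lists fixed before the data were examined.

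The authors deposited 4 peak lists on mouse build mm10 (GRCm38). Per the notes deposited with the files, the peaks of each replicate were derived from its own alignments and a further file, read here as its control, a pooled list was derived from the alignments and such files of both replicates, and a replicated list was derived from the pooled list and both replicates' own lists. The overlap rule behind the replicated list, the peak caller, its version and its threshold are not given in the sources used here. For each peak the deposited lists give, in the order of the narrowPeak layout, a fold enrichment (a linear ratio) and the −log10 of a p-value and of a q-value. These values are the authors', and they were used here to describe, rank and filter peaks within a list. Rows of the replicated list carry the values of the pooled peak: all 30090 replicated peaks on the assembled chromosomes had the position and fold enrichment of a pooled peak. Of them, 86.0% overlapped a peak of both replicates' own lists, 71.7% with at least 50% covered in both, and 172 overlapped neither, so a replicated peak is not always a peak of both lists. The lowest −log10 p in the deposited lists was 2.02 for each replicate, so the lists hold weak peaks: 37.8% of the peaks of replicate 1 and 36.8% of those of replicate 2 had a −log10 q under 2. Read counts and sequencing depth are not part of these lists, so the depth is unknown and no interval or limit that needs it is given. A gene without a peak is a gene without a called peak, and may carry acetylation below the calling threshold. Each replicate is 1 library, and their values are printed side by side. Tests of how gene lists shifted between the replicates, in the closing section, describe these 2 libraries only, and p-values below describe genes within these peak lists; genes are not independent replicates.

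Peaks on chromosomes 1 to 19, X and Y were analysed. Every peak ended within the length of its chromosome in the GRCm38 sequence. Gene models were those of GENCODE M21, with 21853 protein-coding genes. A promoter was the region within 1000 bp of the transcription start site (TSS) of any protein-coding transcript of a gene, and a gene had a promoter peak where a peak overlapped it by at least 1 bp. The height of a promoter was the fold enrichment of its highest peak. Acetylated domains were made by merging replicated peaks across gaps of up to 1000 bp. A gene with several promoters was given the widest domain over any of them, which need not hold its highest peak. Peaks that overlapped several classes were counted as promoter, then exon, intron and intergenic. Distal peaks lay more than 2000 bp from every annotated TSS of any gene type. The expected overlap was taken from 100 random placements on the same chromosomes outside assembly gaps of 1000 bp or more. Promoter CpG content was the observed/expected CpG ratio within 1000 bp of the 5′ end of the gene, and genes were divided into 5 equal classes of it.

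Of the 26 gene lists, 22 were written out as symbols and 4 were taken by symbol pattern. One listed symbol, Drgx, is annotated as Prrxl1 and was matched through a table of gene synonyms. The share of a list's members with a replicated promoter peak was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. Mean log2 height and mean log2 domain width were compared by two-sided permutation tests with 100000 resamples, for the 21 lists with at least 5 members that had a peak. Each gene counted, and the tests were repeated with each peak or domain counted once in the lists and among all genes. P-values were adjusted by the Benjamini-Hochberg method over the lists. Neural lists (5 lists) were compared with non-neural lists (9 lists), spinal with forebrain and midbrain factors, and Hox paralog groups 1 to 9 with 10 to 13, each by a two-sided Fisher's exact test. Odds ratios from tables with an empty cell were computed after adding 0.5 to each cell. Genes were named by a rule fixed in advance: the 12 places with the highest promoter peak, the 12 with the widest domain, the 4 highest members of each list and its first 4 without a peak in list order, the 6 places per replicate with the highest promoter peak that the other lacked, every Hox gene, Xist and 4 Y-linked genes, and the genes nearest the 6 highest distal peaks. Genes on a shared peak counted as 1 place.

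Alternatives were other promoter windows (500 and 2000 bp), stricter thresholds (−log10 q of at least 2 or 10, fold enrichment of at least 4), the pooled list, the intersection of the replicates' lists, an overlap of at least 50%, a single TSS per gene, other merging gaps (0 and 3000 bp), other distances for distal peaks, tests stratified by promoter CpG class, and each replicate alone. The intervals of shares are 95% Wilson intervals over peaks and cover counting error only. Functions were tested on simulated data before use: with 10 lists of 20 genes planted among 21853 genes, 10 of 10 were called for promoter share and 10 of 10 for a 2-fold height difference, and 0 of 10 unplanted lists were called in either test. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.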

Results

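H3K9ac was mapped in the neural tube at embryonic day 12.5, when progenitors and newly born neurons are both present, in 2 pools of embryos. Replicate 1 gave 61692 peaks and replicate 2 gave 63832. Both libraries together gave 80519 pooled peaks, of which 30096 formed the authors' replicated list. The replicated peaks on the assembled chromosomes covered 30.5 Mb, with a median width of 741 bp and a median fold enrichment of 5.10. Fold enrichments throughout are the authors' values, and the sequencing depth is unknown.

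The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 51.0% (95% Wilson interval 50.6 to 51.4%) overlapped a replicate 2 peak, against 2.79% ± 0.07 (SD, 100 random placements) by random placement. Of the replicate 2 peaks, 46.5% (46.1 to 46.9%) overlapped a replicate 1 peak, against 2.70% ± 0.07. The peaks found in a single replicate mostly had a fold enrichment under 5. In replicate 1, 23.4% of the 17449 peaks under 3 and 42.5% of the 29093 peaks of 3 to 5 overlapped the other list. The share was 98.8% for the 8864 peaks of 5 to 10 and 100% for the 6280 peaks of 10 or more. In replicate 2 the same shares were 17.7%, 36.0%, 97.3% and 100%. Across the 13772 genes with a promoter peak in both lists, promoter heights correlated with a Spearman's rho of 0.876 and a Pearson's r of 0.879 on log2 values. This correlation is across genes, which are not independent replicates.

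**Figure D1:**
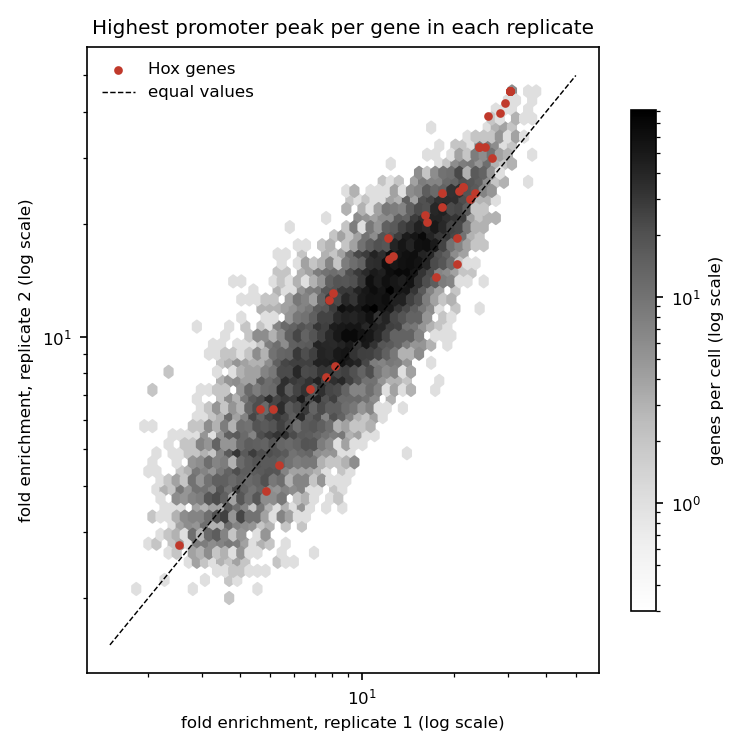
Fold enrichment of the highest promoter peak of each gene in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with grey cells shaded by the number of genes, Hox genes as red points and equal values as a dashed line. Heights followed each other over the 13772 genes, with a rho of 0.876.

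Promoter peaks were found at 14224 genes in replicate 1 and 14315 in replicate 2. Of these, 452 genes had a peak in replicate 1 alone, with a median fold enrichment of 3.09, and 543 in replicate 2 alone, with a median of 3.17. The highest peaks seen in replicate 1 alone lay at the promoters of Sdhaf1 (11.8), Ushbp1 (8.80), Ccdc8 (6.47), Pcdhgb6 (6.18), Pax1 (5.62) and Pgm5 (5.30). Pax1 encodes a transcription factor of the sclerotome. Those in replicate 2 alone lay at Tmem88b (14.5), E130218I03Rik (13.1), Grm6 (6.95), Ptgr1 (6.38), Gm20509 (6.12) and 2610042L04Rik (5.56). For Sdhaf1, Ushbp1, Ccdc8, Tmem88b, E130218I03Rik and Gm20509 the other replicate did have a peak that overlapped the same peak, but outside the promoter window. For Sdhaf1 that peak of replicate 2 reached a fold enrichment of 16.1. Of these genes, Sdhaf1 (with E130208F15Rik), Ushbp1 (with Babam1), E130218I03Rik (with Gm30191 and Zfp593) and Gm20509 (with Khdc3) share their replicated peak with other promoters.

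Acetylation was concentrated at promoters. Promoters held 17144 of the replicated peaks, or 57.0%, against 3.95% ± 0.11 (SD, 100 random placements) by random placement, a ratio of 14.4. Promoter peaks were also the highest and widest, with a median fold enrichment of 9.05 and a median width of 1120 bp. Exons held 7.46% of the peaks against 7.40% at random, introns 19.4% against 32.0%, and intergenic sequence 16.2% against 56.7%. In the pooled list the promoter share was 27.9%, and in the lists of replicate 1 and replicate 2 alone it was 36.3% and 34.7%.

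A replicated promoter peak was found at 13838 of the 21853 protein-coding genes (63.3%). The highest peak of all, with a fold enrichment of 46.4 (37.1 in replicate 1 and 45.3 in replicate 2), covered the promoter of Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, on chromosome 4 from 133750393 to 133757844. Bicral (45.9) and the cytoskeletal actin gene Actb (45.4) followed. Skida1 (44.3), a peak shared by Hoxb3 to Hoxb9 (43.8), Sox4 (43.4), Sfpq (43.3), Mex3b (42.4), Brsk1 (42.3), Msi1 (41.9), Setd1b (41.9) and Actg1 (41.5) completed the 12 highest places. Sox4 encodes a transcription factor of differentiating neurons, and Msi1 an RNA-binding protein of neural progenitors. Peak presence followed promoter CpG content: 6.22% of genes in the lowest CpG class had a replicated promoter peak, then 30.2%, 84.6%, 97.0% and 98.6% in the highest class.

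Genes of the neural lists carried promoter peaks far more often than genes of the non-neural lists. The neural lists were those of progenitor, proneural, progenitor domain, spinal neuron and pan-neuronal genes. Neurotransmitter genes (13 of 17 with a peak) and glial genes (9 of 17) were in neither group. Of the 114 genes of the neural lists, 104 (91.2%) had a replicated promoter peak, compared with 55 of the 161 genes of the non-neural lists (34.2%). The odds ratio was 20.0 (two-sided Fisher's exact test, p = 4.29e-23). The odds ratio within classes of promoter CpG content was lower, at 9.19 (Mantel-Haenszel test).

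All 20 neural progenitor genes had a replicated promoter peak (adjusted p = 0.000526, Fisher's exact test against all other genes, as in the list tests that follow). The highest were at Msi1, at Nr2f1 (38.3), at Hes5 (25.0), a Notch target whose peak also covered the promoter of Pank4, and at Sox2 (23.4), a transcription factor that maintains progenitors. All 24 pan-neuronal genes had one (adjusted exact p = 0.000108), led by Ncam1 (22.5), the neuronal tubulin gene Tubb3 (20.9), Elavl3 (20.4) and Map2 (17.1). Of the 18 proneural and neurogenesis genes, 17 had one (adjusted exact p = 0.00826). The Notch ligand genes Dll1 (18.2) and Dll3 (15.0), with Hes6 (17.1) and Insm1 (16.6), were the highest, and Neurod4 lacked a replicated peak. The proneural call was lost by the exact test with replicate 1 alone (adjusted p = 0.0647), at a −log10 q of at least 10 (0.136), at a fold enrichment of at least 4 (0.0760) and with 50% covered in each replicate (0.407). Both the proneural and the progenitor call were lost within CpG classes, where the proneural odds ratio was 6.49 and the progenitor odds ratio was infinite because no member lacked a peak, so the lost progenitor call does not show a smaller effect.

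Transcription factors of spinal neuron classes were marked at 27 of 30 promoters (adjusted exact p = 0.00324). The highest peaks were at Foxp1 (18.9), a factor of limb-innervating motor neurons, Lbx1 (16.8), a factor of dorsal interneurons, Lhx5 (16.6) and Lhx1 (15.8). Vsx2, Gata3 and Sim1, factors of ventral interneurons, lacked a replicated promoter peak, although the pooled list held weak ones of 3.13, 3.13 and 3.10. The spinal neuron call was lost within CpG classes (odds ratio 1.45). It was also lost with a fold enrichment of at least 4 (adjusted exact p = 0.625), and turned with a −log10 q of at least 10 (adjusted p = 1, odds ratio 0.945). Factors of the dorsoventral progenitor domains had a peak at 16 of 22 promoters and did not pass the test against other genes (adjusted exact p = 0.573). Irx5 (17.9), Irx3 (17.4), Pax3 (10.1) and Msx2 (9.87) had the highest. Dbx1, Dbx2 and Olig2, factors of intermediate and motor neuron progenitors, lacked a promoter peak in each of the 4 lists. Nkx2-2, a factor of the ventral p3 domain, lacked a replicated one. Within CpG classes the progenitor domain factors had fewer peaks than other genes, with an odds ratio of 0.257 that passed the Mantel-Haenszel test.

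Neurotransmitter genes had a peak at 13 of 17 promoters (adjusted exact p = 0.417). The highest peaks belonged to genes of inhibitory transmission, Slc6a1 (10.9), Gad1 (10.7), Slc6a5 (10.4) and Slc32a1 (9.65). Monoaminergic genes were split: Th, Dbh, Ddc and Tph2 lacked a replicated peak, whereas Slc18a2, Slc6a4 and Slc6a3 had one. Glial genes had a peak at 9 of 17 (adjusted exact p = 0.533), with Nfia (28.3), Nfib (20.5), Slc1a2 (15.6) and Glul (12.5) the highest. The peak of Nfia also covered the promoter of E130114P18Rik, and that of Glul the promoter of Teddm2. Olig1 and the myelin genes Mog, Mag and Mobp lacked a replicated peak, whereas the myelin gene Mbp had one.

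Regional identity was compared between spinal factors and factors of the forebrain and midbrain. Of 51 spinal factors, 42 (82.4%) had a replicated promoter peak, compared with 10 of 20 forebrain and midbrain factors (50%) after genes in both lists were left out (odds ratio 4.67, two-sided Fisher's exact test, p = 0.0149). The call was lost with replicate 2 alone (odds ratio 3.38, exact p = 0.0539) and in the pooled list (odds ratio 2.94, p = 0.209). The peaks of forebrain and midbrain factors were also low. Dlx5 (5.10), Otx1 (4.64), Dlx1 (4.61) and Barhl2 (4.28) were the highest, and Foxg1, Otx2, Six3 and Six6 lacked a replicated one. Barhl2 is also in the spinal neuron list and was left out of the comparison of spinal with forebrain and midbrain factors. Against all other genes the 11 of 21 members with a peak did not pass the test (adjusted exact p = 0.452), but the list had fewer peaks with a −log10 q of at least 10 (adjusted p = 1.89e-05) or a fold enrichment of at least 4 (adjusted p = 0.00195). Within CpG classes it also had fewer, with an odds ratio of 0.0316 that passed the Mantel-Haenszel test.

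**Figure D2:**
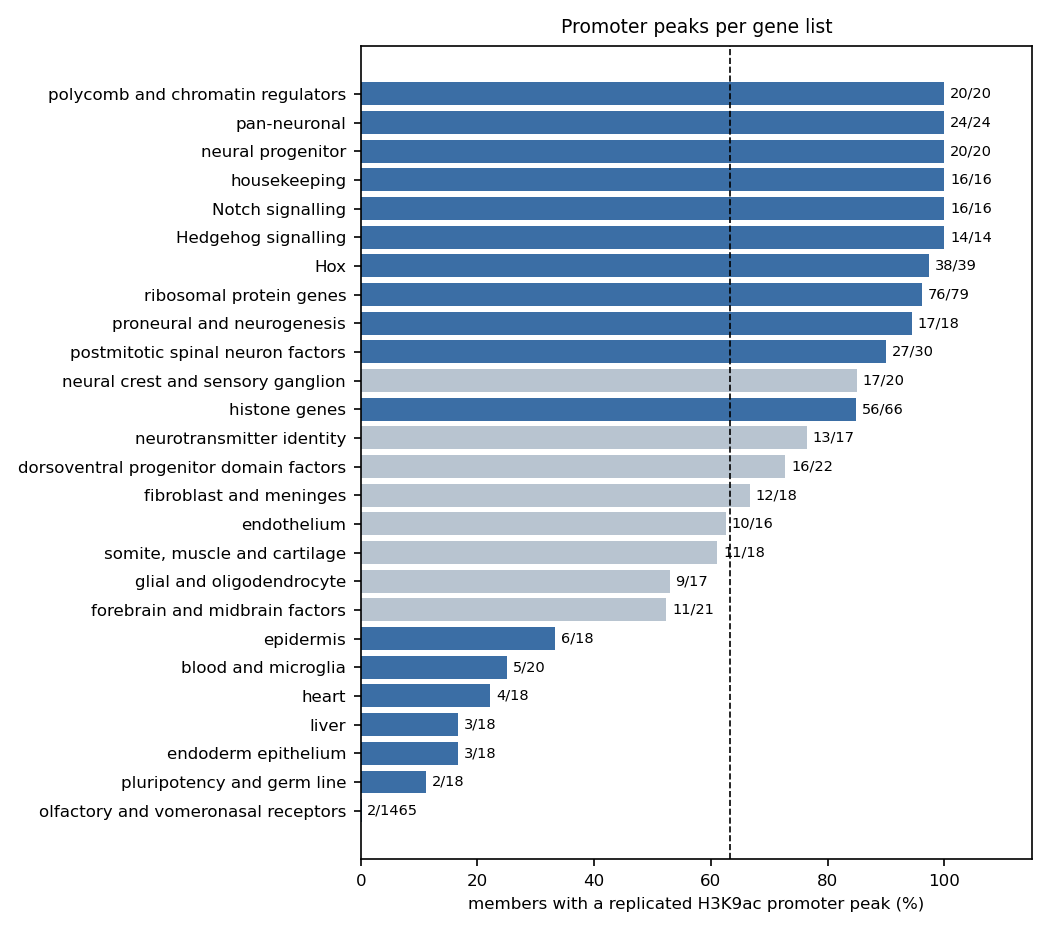
Share of the members of each gene list with a replicated H3K9ac promoter peak (x axis, percent), with the numbers of members with a peak and of all members beside each bar. Dark bars differ from all other protein-coding genes at an adjusted p under 0.05, and the dashed line marks the 63.3% of all protein-coding genes.

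Lists of other tissues fell into groups. Germ line and pluripotency genes had a peak at 2 of 18 promoters, Dazl (5.76) and Esrrb (3.91), and Pou5f1, Nanog, Zfp42 and Dppa3 lacked one (adjusted exact p = 4.54e-05). Liver genes had 3 of 18 (adjusted exact p = 0.000249). Foxa3 (17.4), on a peak that also covered the promoter of Sympk, Prox1 (14.3) and Trf (5.10), on a peak shared with Gm20425, had one, and Alb, Afp, Apoa1 and Apoa2 had none. Endoderm genes also had 3 of 18 (adjusted exact p = 0.000249), at Epcam (6.42), Foxa1 (2.91) and Sox17 (2.80), whereas Cdx1, Cdx2, Vil1 and Cdh17 lacked one. With replicate 2 alone 9 endoderm genes had a peak and the call was lost (adjusted exact p = 0.292). Heart genes had 4 of 18 (adjusted exact p = 0.00157), among them Myl3 (13.5), on a peak shared with the promoter of Pth1r, Ryr2 (11.0), Gata6 (3.45) and Hand2 (3.13), and Nkx2-5, Myh6, Myh7 and Tnnt2 had no replicated peak. With replicate 2 alone the heart list had 8 (adjusted exact p = 0.123). Blood and microglia genes had 5 of 20 (adjusted exact p = 0.00156), led by Klf1 (8.06), Tal1 (4.94), Gypa (4.80) and Epor (4.09), whereas Gata1, Alas2, Hba-x and Hbb-bh1 lacked one. Members of this list need not be confined to blood, and which cells gave their peaks was not tested. Epidermal genes had 6 of 18 (adjusted exact p = 0.0180), with Krt10 (8.55), Perp (5.26), Ovol1 (4.77) and Dsp (3.80) the highest and no replicated peak at Krt5, Krt14, Krt15 or Krt8. The epidermal call was lost by the exact test with replicate 2 alone (8 of 18, adjusted p = 0.123), in windows of 2000 bp (0.292) and without genes that share their peak (0.0757).

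Within CpG classes the calls for blood, liver and epidermis were lost. The odds ratio moved from 0.193 to 0.794 for blood, from 0.116 to 0.180 for liver and from 0.289 to 0.162 for epidermis, so the lost epidermis call does not show a smaller effect. The heart call was lost in the pooled list (adjusted exact p = 0.173).

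Mesenchymal, vascular and neural crest genes did not pass the test against all other genes. Somite, muscle and cartilage genes had a peak at 11 of 18 promoters (adjusted exact p = 0.880), with Uncx (14.6), the cartilage collagen gene Col2a1 (13.2), Scx (9.38) and Tcf15 (7.24) the highest, and Meox1, Myf5, Myog and Acta1 without one. Fibroblast and meninges genes had 12 of 18 (adjusted exact p = 1), led by Lama1 (16.9), Twist1 (12.8), Foxc1 (11.0) and Foxd1 (9.21), and Col1a2, Col3a1, Dcn and Lum lacked one. Endothelial genes had 10 of 16 (adjusted exact p = 1), with Kdr (7.40), Egfl7 (7.14), Sox7 (5.26) and Cldn5 (5.10) the highest and no replicated peak at Pecam1, Cdh5, Tek or Tie1. Neural crest and sensory ganglion genes had 17 of 20 (adjusted exact p = 0.0829), led by Pou4f1 (15.6), Mpz (13.4), whose peak also covered the promoter of Sdhc, Tfap2b (11.8) and Foxd3 (9.87), with Phox2b, Plp1 and Avil unmarked. These lists were written for mesenchymal, vascular and neural crest tissue, but their members need not be confined to it. Which cells gave their peaks was not tested.

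Signalling and general lists were marked almost throughout. All 16 Notch genes (adjusted exact p = 0.00189), all 14 Hedgehog genes (adjusted p = 0.00550), all 20 polycomb and chromatin regulators (adjusted p = 0.000526) and all 16 housekeeping genes (adjusted p = 0.00189) had a replicated promoter peak. The highest were Hes5, Rbpj (23.7), Maml1 (21.6) and Dll1 in the Notch list, and Ptch1 (33.1), Gas1 (27.5), Cdon (22.2) and Smo (20.0), the receptor, co-receptors and transducer of Hedgehog signals, in the Hedgehog list. Ep300 (34.7), Hdac2 (29.8), Ezh2 (28.0) and Chd7 (27.8) led the chromatin regulators, and Actb, Ywhaz (37.4), Ubc (27.8), whose peak also covered the promoter of Gm10382, and Hsp90ab1 (26.7) the housekeeping genes. Ribosomal protein genes had 76 of 79 (adjusted exact p = 5.79e-11), led by Rpl17 (30.4), Rps6 (28.3), Rps19 (28.2) and Rpl19 (28.0), and the 3 without a peak were Rpl10l, Rpl39l and Rpl3l. Histone genes had 56 of 66 (adjusted exact p = 0.000526), led by Hist1h1e and Hist1h2be on a shared peak (18.3), Hist3h2a (15.0, shared with Trim17) and Hist2h4 (14.3), with no replicated peak at Hist1h1d, Hist1h1t, Hist1h2aa or Hist1h2ao. Within CpG classes the histone result turned, with an odds ratio of 0.174 that passed the Mantel-Haenszel test, and the ribosomal call was lost (odds ratio 2.48). The Hedgehog and chromatin regulator calls were also lost there, but their odds ratios were infinite because no member lacked a peak, so these losses do not show smaller effects. By the exact test, the Notch call was lost with a single TSS per gene (14 of 16, adjusted p = 0.0539), the Hedgehog call at a −log10 q of at least 10 (12 of 14, adjusted p = 0.0782) and the histone call without genes that share their peak (adjusted p = 0.171). Olfactory and vomeronasal receptor genes had 2 of 1465 (odds ratio 0.000647), Vmn1r4 (10.5), on a peak shared with the promoter of Nt5c3, and Olfr94 (5.59). The first of the unmarked receptors in list order were Olfr1, Olfr10, Olfr1000 and Olfr1002.

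Among genes with a replicated promoter peak, the geometric mean fold enrichment was 20.0 for Hox genes (log2 difference from all such genes 0.88, with genes that share a peak counted separately), 19.6 for chromatin regulators (0.86), 18.0 for housekeeping genes (0.73), 17.8 for ribosomal protein genes (0.72) and 15.6 for neural progenitor genes (0.53). Adjusted p-values by permutation were 3.00e-05, 3.00e-05, 0.000513, 3.00e-05 and 0.00349, and 3.00e-05 is the smallest that the permutations could give after adjustment. With each peak counted once, the 25 Hox peaks had a geometric mean of 14.6 (log2 difference 0.45, adjusted permutation p = 0.00624). Spinal neuron factors were lower than other marked genes, at 6.44 (log2 difference -0.75, adjusted p = 3.00e-05 by permutation), as were progenitor domain factors at 6.70 (-0.69, adjusted p = 0.000805) and neurotransmitter genes at 6.68 (-0.70, adjusted p = 0.00199). Proneural genes were lower at 8.21 (-0.40, adjusted permutation p = 0.0460). That call was lost with either replicate alone (adjusted permutation p = 0.254 with replicate 2 and 0.0745 with replicate 1), in windows of 500 bp (0.123) and with summed fold enrichment (0.104). It was also lost with each peak counted once (adjusted permutation p = 0.0661), although the log2 difference there was still -0.38. Pan-neuronal genes did not pass the test (11.1, log2 difference 0.03, adjusted permutation p = 0.831), nor did Notch (12.9, adjusted p = 0.226), Hedgehog (12.1, adjusted p = 0.486) and glial genes (9.32, adjusted p = 0.462). The marked members of the 5 non-neural lists that could be tested were low, with geometric means of 4.32 for epidermis, 4.62 for endothelium, 4.71 for blood, 6.01 for somite and 6.54 for fibroblast genes (adjusted p from 3.00e-05 to 0.00210 by permutation). Liver, heart, endoderm and germ line lists had fewer than 5 marked members and were not tested. Forebrain and midbrain factors had the lowest, 3.80 (log2 difference -1.51, adjusted permutation p = 3.00e-05), and neural crest (6.79) and histone genes (7.09) were lower too (adjusted p = 0.000630 and 3.00e-05), the histone call being lost with summed fold enrichment (adjusted p = 0.472). Height also varied with promoter CpG content. From the lowest to the highest CpG class, marked genes had a median fold enrichment of 8.49, 6.49, 8.63, 11.8 and 15.8. The permutation tests of height here, and of domain width below, did not take CpG class into account. How far CpG content accounts for these differences between lists was not tested.

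The median domain over a marked promoter was 1727 bp. Neural progenitor genes had a geometric mean width of 5776 bp (log2 difference 1.81, adjusted p = 5.25e-05 by permutation, the smallest the permutations could give after adjustment). Pan-neuronal genes had 3410 bp (1.05, adjusted permutation p = 5.25e-05), Notch genes 3443 bp (adjusted p = 0.000210) and spinal neuron factors 2498 bp (0.60, adjusted p = 0.00317). Proneural genes (2367 bp, adjusted permutation p = 0.0346) and neural crest genes (2427 bp, adjusted p = 0.0254) were also wider, calls that were lost with replicate 1 alone (adjusted p = 0.0953 and 0.125), the second also with replicate 2 alone (adjusted p = 0.0673) and without merging (adjusted p = 0.710). Chromatin regulators (2748 bp, adjusted permutation p = 0.00220), Hedgehog (2655 bp, adjusted p = 0.0139), housekeeping (2592 bp, adjusted p = 0.0125), ribosomal protein (2397 bp, adjusted p = 5.25e-05) and histone genes (2290 bp, adjusted p = 0.00102) were wider too. With replicate 1 alone the Hedgehog (adjusted permutation p = 0.0646), housekeeping (adjusted p = 0.0675) and histone calls (adjusted p = 0.0627) were lost, and the histone result was also lost with each domain counted once (adjusted p = 0.116) and turned without merging (adjusted p = 0.000210). Domains over forebrain and midbrain factors (626 bp), blood genes (635 bp) and epidermal genes (677 bp) were narrower (adjusted permutation p = 0.000210, 0.00725 and 0.00571), the blood call being lost with merging gaps of 3000 bp (adjusted p = 0.587). The widest domains outside the Hox clusters covered Pou3f3 (21928 bp), Bahcc1 (21299 bp), Mllt10 and Skida1 (20585 bp), Zfhx3 (19656 bp), Meis2 (17183 bp), Lhx5 (17043 bp) and Zmynd8 (16211 bp). Pou3f3, Zfhx3, Meis2 and Lhx5 encode homeodomain transcription factors.

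The Hox genes, which pattern the body axis, had replicated promoter peaks at 38 of 39 members (adjusted exact p = 6.67e-06) and the widest domains in the genome. A domain of 94608 bp on chromosome 6 covered Hoxa1 to Hoxa11, with 5730596B20Rik and Gm28308. Domains of 90252 bp on chromosome 11 and 83545 bp on chromosome 15 covered Hoxb2 to Hoxb9 and Hoxc4 to Hoxc10. On chromosome 2 the Hoxd cluster was divided, with domains of 22211 bp over promoters of Hoxd4 and Hoxd3, 15413 bp over Hoxd8 and the highest promoter peak of Hoxd3, and 14768 bp over Hoxd9 and Hoxd10. The geometric mean width of 28901 bp (log2 difference 4.13, adjusted permutation p = 5.25e-05) counts genes that share a domain separately, and the 15 Hox domains counted once had 6231 bp (log2 difference 1.97, adjusted permutation p = 3.50e-05). In paralog groups 11 to 13, Hoxd11 reached 16.0, Hoxc11 9.97, Hoxa11 8.15, Hoxc13 6.09, Hoxc12 5.44, Hoxd13 4.94, Hoxd12 3.94 and Hoxb13 2.80, and Hoxa13 was the 1 Hox gene without a replicated promoter peak. Among the anterior genes, Hoxb1 (7.40) and Hoxd1 (8.23) were low, whereas Hoxa1 reached 17.2, Hoxa2 28.3 and Hoxb2 41.2. Single peaks covered Hoxa3, Hoxa4, Hoxa5, Hoxa6, Hoxa7 and Hoxa9 (32.7), Hoxc9 and Hoxc10 (40.5), and Hoxc5 and Hoxc6 (20.4). In the lists of replicate 1 and replicate 2, the Hoxc10 promoter reached only 12.6 and 16.4, compared with 29.2 and 42.3 for Hoxc9. Hoxa10 reached 25.8, Hoxc8 18.3, Hoxc4 16.8, Hoxd3 33.1, Hoxd4 21.9, Hoxd8 25.7, Hoxd9 21.1 and Hoxd10 11.7. A peak was present at 27 of 27 genes of groups 1 to 9 and 11 of 12 of groups 10 to 13 (two-sided Fisher's exact test, p = 0.308). With a single Hox gene lacking a peak, this test could not have passed and shows no equality. With peaks of a fold enrichment of at least 4, the second group had 9 of 12 (exact p = 0.0241). That p-value counts genes on a shared peak, such as Hoxb3 to Hoxb9, as separate observations. The tests of paralog groups were not repeated with each peak counted once, so this difference may rest on the shared peaks.

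**Figure D3:**
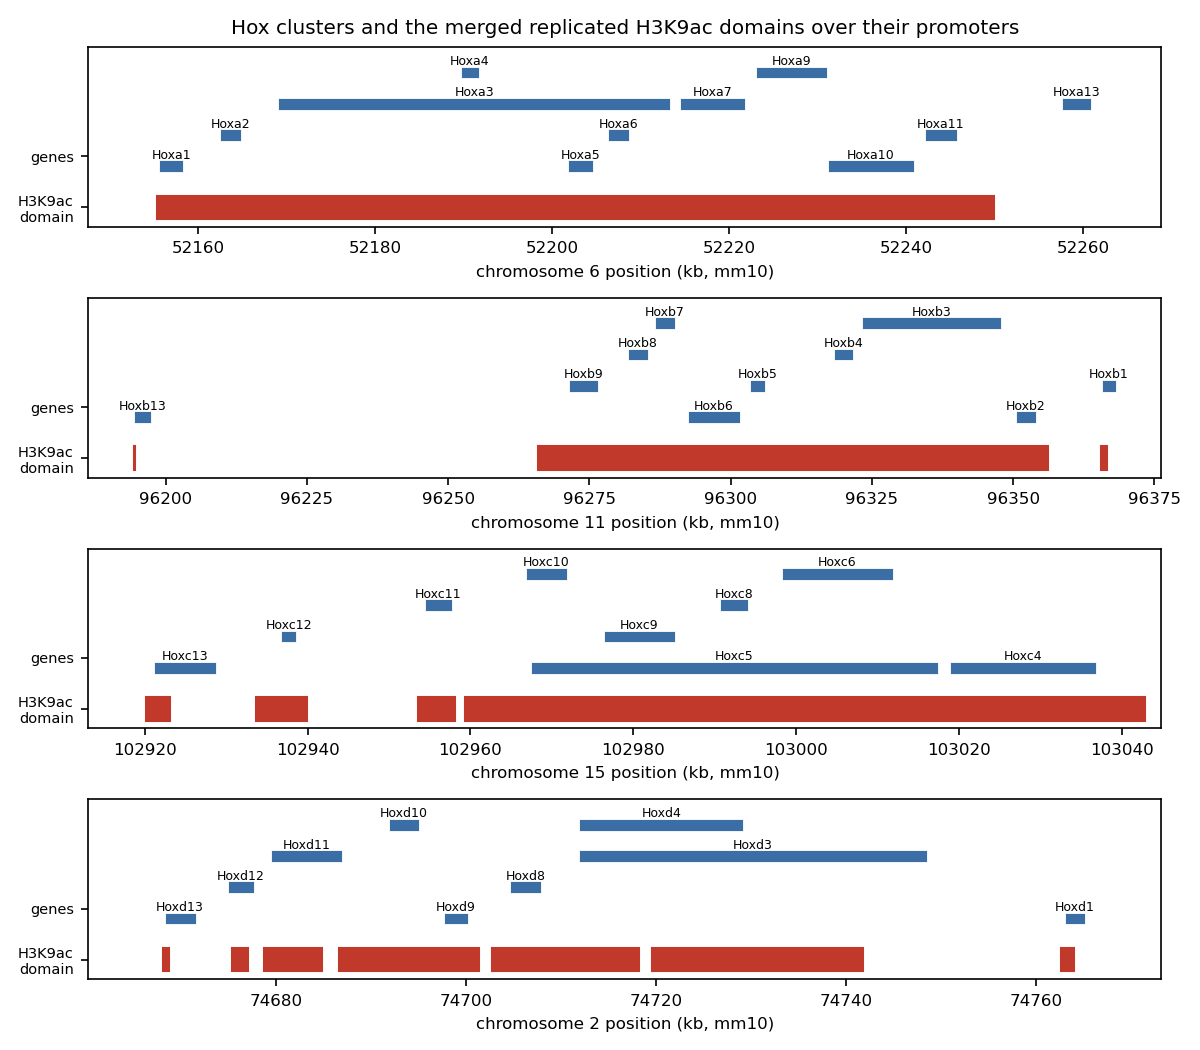
The 4 Hox clusters, with genes in blue and the merged replicated H3K9ac domains over their promoters in red, by chromosome position in kb (mm10). Single domains span Hoxa1 to Hoxa11, Hoxb2 to Hoxb9 and Hoxc4 to Hoxc10, and the Hoxd cluster is divided into several.

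Distal peaks, more than 2000 bp from every TSS, numbered 8497 (28.2% of replicated peaks). Genes of the neural lists had a mean of 2.84 ± 3.85 (SD, n = 114 genes) of them within 100 kb, compared with 1.74 ± 2.67 (SD, n = 161 genes) for the non-neural lists (two-sided permutation test, p = 0.00456). Across all protein-coding genes the mean was 1.44 and the median 0, so the means of both groups lay above that of all genes. The call, though not the direction, was lost within 200 kb (permutation p = 0.184) and for peaks more than 5000 bp from a TSS (p = 0.0760). The highest distal peak, at 26.0 (20.2 in replicate 1 and 25.1 in replicate 2), lay in an intron of Hoxc4 on chromosome 15 from 103024147 to 103030726. That peak was 3669 bp from a TSS and lay inside the domain of 83545 bp over Hoxc4 to Hoxc10, so it is not a separate domain. The next, at 22.4, was intergenic on chromosome 15 from 85669291 to 85673341, with Ppara as the nearest protein-coding gene at 62223 bp. Others were intergenic near Zfp869 (21.1, 5466 bp from a TSS) and Cbx8 (20.1, 15279 bp), and in exons of Pura (18.8, 4872 bp) and Prdm2 (18.7, 32517 bp).

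The sex-linked genes had weak marks in these mixed-sex pools. Xist, the long noncoding RNA of the inactive X chromosome, had a replicated peak of 3.78 at one annotated start, which was called in replicate 1 (3.94) and not in replicate 2. Of the Y-linked genes, Kdm5d (3.45, called in replicate 2 at 3.89 and not in replicate 1) and Uty (3.45, called in both) had a replicated promoter peak, and Ddx3y and Eif2s3y did not.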

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

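Of the 80505 pooled peaks on the assembled chromosomes, 20862 (25.9%) overlapped no peak of either replicate's own list. They were weak and narrow, with a median fold enrichment of 2.49, a highest value of 3.95 and a median width of 194 bp, compared with a median fold enrichment of 3.13 for the other pooled peaks. No explanation was tested for them. A further 6 replicated peaks lay on sequence not placed on a chromosome and were left out.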

How the results depend on the processing

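Only the settings without genes that share their peak, which can remove only genes with a peak, and with each peak or domain counted once were chosen after the results were seen. Of 621 alternative values for 80 results, 542 were counted as unchanged, 42 lost their call, 9 gained one, 24 moved and 4 turned. Those counted as unchanged kept their direction and side of the threshold, or moved by less than their spread. They also include every count of genes with a promoter peak, 13838 in the main setting. That count ran from 12688 at a −log10 q of at least 10 to 14724 in the pooled list. The cause was not tested for any of the changes, and the unknown depth limits what a missing peak shows. No paired analysis was possible because the series has 1 group. Values for gene lists are adjusted p-values.

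Overlap of replicate 1 and replicate 2 peaks was 44.9% and 39.1% with 50% of the peak covered, 33.0% and 31.9% with 50% of both, 64.7% and 58.4% at a −log10 q of at least 2, 94.7% and 86.2% at 10, 50.6% and 47.6% with equal numbers of peaks, and 47.1% and 45.1% after merging. The rho of heights was 0.807 with summed fold enrichment, 0.917 with −log10 p and 0.869 in windows of 500 bp. The promoter share was 53.5% with 500 bp, 62.7% with 2000 bp, 83.5% at a −log10 q of at least 10, 59.6% after merging, 27.9% in the pooled list and 34.7 to 36.3% with single replicates. The difference in peak presence between the highest and lowest CpG classes was 91.0 percentage points with 500 bp and 89.0 in the pooled list.

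At a −log10 q of at least 10, Hox groups gave exact p = 0.0241, and promoter share gave 0.136 for proneural, 1 for spinal neuron (turned), 1.89e-05 for forebrain and midbrain and 0.0782 for Hedgehog genes. At a fold enrichment of at least 4, Hox groups gave p = 0.0241 by Fisher's exact test, and share gave 0.0760 for proneural, 0.625 for spinal neuron and 0.00195 for forebrain and midbrain genes. Within CpG classes share gave 0.0846 for progenitor, 0.203 for proneural, 0.00231 for progenitor domain (turned), 0.467 for spinal neuron, 4.68e-13 for forebrain and midbrain, 0.759 for blood, 0.0846 for liver, 0.140 for epidermis, 0.352 for Hedgehog, 0.226 for chromatin, 5.00e-07 for histone (turned) and 0.163 for ribosomal genes. Share also gave 0.407 for proneural genes with 50% covered in each replicate, 0.292 for epidermis with 2000 bp, 0.0539 for Notch with a single TSS, 0.173 for heart in the pooled list, and, without shared peaks, 0.0757 for epidermis and 0.171 for histone genes. The odds ratio of spinal against forebrain and midbrain factors was 2.94 in the pooled list.

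Height gave 0.123 for proneural genes with 500 bp, and, with summed fold enrichment, 0.104 for proneural and 0.472 for histone genes, and 0.0661 for proneural genes with each peak counted once. Width without merging gave 0.710 for neural crest, 0.0343 for endothelium and 0.000210 for histone genes (turned), with each domain counted once 0.116 for histone genes, and with gaps of 3000 bp 0.000327 for progenitor domain, 0.0393 for neurotransmitter and 0.587 for blood genes. The difference in distal peaks was 0.798 within 200 kb and 0.527 beyond 5000 bp.

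With single replicates the spinal odds ratio was 3.38 to 4.67. Share gave 0.0389 to 0.123 for heart, 0.00366 to 0.123 for epidermis, 0.000179 to 0.292 for endoderm and 0.0183 to 0.0647 for proneural genes, and proneural height 0.0745 to 0.254. Width gave 0.0271 to 0.316 for neurotransmitter, 0.0673 to 0.125 for neural crest, 0.0201 to 0.0675 for housekeeping, 0.0155 to 0.0953 for proneural, 0.0335 to 0.0646 for Hedgehog and 0.00188 to 0.0627 for histone genes.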

Other observations

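The tests of gene families by symbol stem, of shifts between the replicates and of the dorsal against ventral split were chosen only after the results were seen. Gene families, including some that also make up fixed lists, were compared by symbol stem. Of 111 stems with at least 20 protein-coding genes, 51 had replicated promoter peaks more often and 32 less often than other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). All 41 Zbtb genes, which encode zinc-finger transcription factors, had one (adjusted exact p = 4.20e-08), as did all 26 Cdk genes (adjusted p = 3.02e-05) and all 28 Polr genes of the RNA polymerases (adjusted p = 1.01e-05). Semaphorin genes, which guide axons, had one at 19 of 20 (adjusted exact p = 0.00320). At the other end, 0 of the 22 Pcdhb genes of the clustered protocadherins had one (adjusted exact p = 1.67e-09). Keratin genes had 4 of 53 (adjusted exact p = 3.79e-16), cytochrome P450 genes 23 of 100 (adjusted p = 3.52e-15) and defensin genes of the Defb stem 0 of 42 (adjusted p = 1.05e-17). The tests of families did not take promoter CpG class into account, although peak presence followed it. How far CpG content accounts for the differences between families was not tested.

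More genes of the neural lists than of the non-neural lists had a replicated promoter peak. Promoter CpG content as the whole cause is argued against by the odds ratio of 9.19 within CpG classes, although it was 20.0 without them. CpG content was measured at the 5′ end of each gene, so a gene marked at another promoter may be in the wrong class. If loci used in the tissue are acetylated more widely, neural genes should also have more distal peaks. They had 1.10 more within 100 kb than genes of the non-neural lists (permutation p = 0.00456). The non-neural mean of 1.74 was itself above the 1.44 of all genes, a difference that was not tested. Smaller differences at 200 kb (0.798, permutation p = 0.184) and beyond 5000 bp (0.527, p = 0.0760) kept the direction but not the call. Acetylation of loci used in the tissue therefore remains a candidate explanation, with a call that depends on the distances chosen. No second tissue was analysed here. Within CpG classes the progenitor domain factors went the other way, with an odds ratio of 0.257. That value is against all other genes, not the non-neural lists, and without CpG classes it was 1.55.

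Genes of some lists ranked higher in replicate 1 and genes of others in replicate 2, but none of 21 lists passed the adjustment. The lowest adjusted p was 0.336, for fibroblast genes (median shift of -7.26 percentile points, replicate 2 minus replicate 1) and proneural genes (7.42), with unadjusted p-values of 0.0300 and 0.0320 against 10000 random lists matched on rank. Somite and fibroblast genes together shifted by -7.14 (permutation p = 0.00660 against 10000 random lists matched on rank, and the same when also matched on CpG class), but a bootstrap over their 21 genes gave -9.10 to 1.22, so neither a bias by peak height or CpG nor its absence was shown. Endothelial, blood and neural crest genes shifted by -0.0218 (bootstrap -1.78 to 1.5, inside the -3.44 to 3.26 of random lists) and so gave no sign of more non-neural tissue of every kind in the pool of replicate 1, but the difference from the mesenchymal genes had an interval of -10.0 to 1.86, which leaves this open. More surrounding mesenchyme in that pool also stays open, since mesenchymal and neural genes with a peak in a single replicate gave an odds ratio of 4 on 15 genes (Fisher's exact test, p = 0.315).

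Ventral progenitor domain factors lacked promoter peaks more often than dorsal ones on 1 way of splitting them: 10 of 11 dorsal factors had a replicated peak, compared with 4 of 9 ventral ones (Fisher's exact test, p = 0.0498, not adjusted, on a split made after the values were seen). The factors counted as ventral without a peak were Olig2, Nkx2-2, Nkx2-9, Dbx1 and Dbx2, and without Dbx1 and Dbx2, which mark intermediate progenitors, 4 of 7 had a peak and the difference did not pass (Fisher's exact test, p = 0.245). Promoter CpG content as the whole cause of this difference was not decided. From the shares of their CpG classes, 7.85 of the 9 ventral and 9.91 of the 11 dorsal factors would have a peak. The one-sided exact probability of 4 or fewer ventral ones was 0.000192 (0.00409 without Dbx1 and Dbx2). That probability is too small to the extent that the split followed the values, so it cannot exclude CpG content. Dbx1, Olig2 and Nkx2-2 lie in the CpG class in which 97.0% of genes had a peak, but Nkx2-9 and Dbx2 in those with 84.6% and 30.2%. Within CpG classes the whole progenitor domain list, fixed beforehand, had an odds ratio of 0.257. The list thus had fewer peaks than other genes of its CpG classes, but that value does not compare dorsal with ventral factors. A smaller share of the tissue in ventral domains, which was not tested, stays open.

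Binding sites of proneural E-box, homeodomain and SOX factors were counted in 5588 distal replicated peaks and in as many nearby windows matched for GC content to 2 percentage points. The prediction, that each of 4 sites would exceed 95% of the sites of the same base composition, held for 1 of the 4. The homeodomain site TAATTA was 1.72 times as frequent in peaks as in the background (513 and 299 counts), above all 13 sites of the same composition, whose median was 1.27 and highest 1.70. Ratios were 1.13 for the E-box CAGCTG (above 92.7% of such sites), 0.942 for the E-box CAGATG (above 56.3%) and 1.08 for the SOX site ACAATG (above 73.7%). Enrichment of all these sites together was thus neither shown nor excluded.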
